A study of Oryza sativa Indica Group with 9 samples.

How the data were processed

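Bisulfite sequencing libraries were made from total genomic DNA of rice plants of the cultivar MR219, extracted with a Qiagen plant mini kit and prepared with methylated adaptors, per the labels' protocols. The instrument was an Illumina MiSeq, per the series' design text. The submitters' processing notes name Trimmomatic 36.0 for trimming and Bismark 16.3 for alignment and calling, and per the file headers the deposited calls came from the Bismark methylation extractor, version 0.16.3. Trimming and alignment settings, the treatment of PCR copies and the origin of the plastid reference sequence are not given in the sources used here. The sequence is named MR219 chloroplast in the files, and positions are given as there, counted from 1.

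The deposited files, 3 for each of the 9 libraries, list single cytosine calls: each line gives a read name, a state (methylated or unmethylated), the position and a letter for context and state. A line therefore is neither a count nor a percentage, and every level here was computed from these calls as methylated calls over all calls of a context, as a percent. No percentage made by the authors was used. Calls under the same read name were taken as a read pair, since they span up to 791 bp. All read names came from 1 run and 1 lane, so no sequencing batch was available to separate libraries. A cytosine was assigned the context of most of its calls. Calls of another context at the same position numbered 5024 of 14511573 and were left out of tests per cytosine and window. The strand of a read pair was inferred from adjacent CG positions and was found for 99.2% of pairs.

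Groups came from the labels. Levels were compared across the 3 groups by an exact permutation test of the between-group sum of squares over all assignments of the 9 libraries (smallest p 0.00357), and pairwise by a two-sided exact permutation test (smallest p 0.1). Differences within libraries were compared by an exact sign-flip test (smallest p 0.00391). Windows of 1000 bp with at least 50 calls, and cytosines with at least 10 calls, in every library were compared with limma 3.58.1 in R 4.3.3 on log2 odds with 0.5 added to each count, weighted by inverse binomial variance, all 3 groups in a single fit without a replicate block. Benjamini-Hochberg adjustment was made per contrast and context, with a threshold of 0.05. Methylated cytosines were called by a one-sided exact binomial test against the level of the same library and context, at an adjusted threshold of 0.01. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Depth per library is given with the results. Deeper libraries (young leaf) have smaller counting errors, and intervals are 95% Wilson intervals. A share of 0 allows up to 3 counts of the total.

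The text names, per contrast, the 5 windows and the 5 cytosines with the largest absolute log2 odds ratio past the threshold, all contexts together. The rule also asked for the 10 highest cytosines among those called methylated in all 3 libraries of a group, of which there were 0. Tests, this rule and most alternatives were fixed before the data were examined. Alternatives were other coverage minimums, window sizes, added counts, weights, models, thinned calls, identical read pairs counted a single time, read pairs rich in methylated CHH calls left out, a replicate block and each library left out. The labels give the groups shared replicate numbers without a stated link. Whether these pair the libraries was checked by correlating deviations from the group mean over CG windows. Grain and old leaf libraries of the same number correlated at 0.126, 0.159 and 0.163, and those of different numbers at -0.213 to 0.0635. However, grain and young leaf libraries of different numbers correlated at up to 0.19. The values therefore do not decide whether the numbers pair grain and old leaf libraries, and the main tests took no pairing. Grain and young leaf libraries of the same number correlated at -0.163 to -0.104, and old and young leaf libraries at -0.022 to 0.0638, so no pairing was taken there. The block was fitted over all 9 libraries, and its calls had been seen before the check was read by contrast. Added after the data had been seen were levels without read pairs with at least 50% of 2 or more CG calls methylated, thinned calls at cytosines, and the class of CG-methylated read pairs.

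The test per window was checked on simulated data of 2 kinds. Where read pairs were shuffled between libraries within bins, 0 windows were called in each contrast and context, but this leaves counting noise only and says nothing about the spread between libraries. In the other kind, counts were drawn with the mean spread seen within groups, independently for each window, so shifts of a whole library were not covered. With 20 of 114 CG windows changed by an odds ratio of 4, 7 were recovered between old and young leaf and 7 between grain and young leaf, and of 20 changed by an odds ratio of 2, 4 and 7 were recovered. For CHH, 14 and 13 of 20 were recovered at an odds ratio of 4. Among unchanged windows at most 4 were called, for CG between old and young leaf, and 3 were called for CHH between grain and young leaf. In this simulation the test therefore missed many differences of this size. It also made false calls, for CG between old and young leaf 4 beside the 4 and 7 recovered. The data gave 68 CG windows in that contrast, whereas the simulation changed only 40. Neither the share missed nor the share of false calls therefore carries over to the data. To look for a library deposited a second time, the numbers of read pairs starting in each window were compared between the libraries of a group by a chi-square test. No pair of libraries agreed within the counting noise of read pairs, PCR copies aside, the closest pair having a chi-square over degrees of freedom of 1.47, so none were merged.

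An annotation of this plastid sequence was not used here. The gene table at hand belongs to another assembly, so no gene was assigned to a position, and the comparisons by gene, by gene list and of genes with spacers that had been planned were left out. Mitochondrial DNA was not analysed here.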

Results

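Plastid DNA methylation was measured by bisulfite sequencing in rice (Oryza sativa, indica group) of the cultivar MR219. Bisulfite converts unmethylated cytosine, which is then read as thymine, whereas methylated cytosine is still read as cytosine. Cytosines were classed by the bases that follow them as CG, CHG or CHH, where H stands for A, C or T. The series held 9 libraries in 3 groups of 3. Grain and old leaf were both taken at the ripening stage, 125 days after germination, and young leaf was taken at the vegetative stage, at labelled ages of 31, 32 and 33 days. In the contrast of old with young leaf, days after germination and growth stage differed together, so neither was separated from the age of the leaf itself. The contrast of grain with old leaf concerned tissue at the same age, and in the contrast of grain with young leaf tissue and age differed together. Nothing in the labels said whether the 3 libraries of a group came from separate plants, so p-values measured only the spread between these libraries.

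The files gave 14511573 cytosine calls on 300549 read pairs. Grain libraries held 757476 to 1089286 calls, old leaf libraries 871634 to 1007812 and young leaf libraries 2301098 to 4036438. The median depth of a CG cytosine was 17 to 25 calls in grain, 20 to 23 in old leaf and 31 to 85 in young leaf. Calls fell on 43215 cytosines of the MR219 plastid sequence, at positions 1 to 113691. Of these, 7012 were CG, 5622 CHG and 30581 CHH cytosines. At least 10 calls in every library were reached at 4388 CG, 3508 CHG and 15107 CHH cytosines.

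Old leaf had higher methylation levels on the plastid sequence than young leaf in all 3 contexts. The CG level was 3.69% ± 0.409 (SD, n = 3) in old leaf and 1.18% ± 0.255 (SD, n = 3) in young leaf, a ratio of 3.11. The CHG level was 2.74% ± 0.266 in old leaf and 0.927% ± 0.199 in young leaf, a ratio of 2.96. The CHH level was 0.382% ± 0.0306 in old leaf and 0.257% ± 0.0156 in young leaf, a ratio of 1.49. In each context the lowest old leaf library lay above the highest young leaf library, for CG at 3.26% and 1.48%. As a mean over cytosines with at least 5 calls the CHH ranges overlapped. The lowest old leaf library was then at 0.337% and the highest young leaf library at 0.349%. The two-sided exact permutation p for 3 libraries against 3 was 0.1 in each context, the smallest this design allows, with an adjusted value of 0.129 over 9 comparisons. Without read pairs with at least 50% of 2 or more CG calls methylated, the levels in old and young leaf were 0.26% and 0.185% for CG, 0.267% and 0.186% for CHG, and 0.215% and 0.196% for CHH, the last with overlapping ranges.

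Grain had lower CHG and CHH levels than old leaf of the same age. The CHG level in grain was 1.11% ± 0.351 (SD, n = 3), 0.405 times that of old leaf, and the CHH level was 0.225% ± 0.00444, 0.588 times that of old leaf. The ranges of the libraries did not overlap in either context, with an exact permutation p of 0.1 and an adjusted value of 0.129. They did overlap without read pairs with at least 50% of 2 or more CG calls methylated, at 0.232% against 0.267% for CHG and 0.206% against 0.215% for CHH. The CG level in grain was 2.53% ± 1.04 and overlapped that of old leaf, with an exact permutation p of 0.3. Grain replicate 1 stood at 3.73% (95% Wilson interval 3.63% to 3.83%), against 1.88% and 1.99% in the other 2 grain libraries. Such intervals cover counting error only, since calls on the same read pair are not independent.

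Grain had a higher CG level than young leaf, by a ratio of 2.14, and a slightly lower CHH level, by a ratio of 0.875. Neither range overlapped, with an exact permutation p of 0.1 for both. As a mean over cytosines the CG ranges did overlap. With at least 10 calls the lowest grain library was at 1.98% and the highest young leaf library at 2.08%. With at least 5 calls these libraries were at 1.84% and 2.19%. The CHG levels of grain and young leaf overlapped, with a ratio of 1.2 and an exact permutation p of 0.5. Without grain replicate 1 the CHG difference turned from 0.184 to -0.0182 percentage points. With the level taken as the mean over cytosines of at least 5 calls it was -0.0936 points. The CHH difference of -0.0322 points turned to 0.00527 points when read pairs with 3 or more methylated CHH calls were left out, and to 0.0104 points without read pairs with at least 50% of 2 or more CG calls methylated.

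Across the 3 groups together, levels differed in each context by an exact permutation test. The p-values were 0.0179 for CG, 0.0179 for CHG and 0.00357 for CHH, the last being the smallest possible, with adjusted values of 0.0179, 0.0179 and 0.0107. For CG the adjusted value was 0.05 without old leaf replicate 1, 0.0536 without old leaf replicate 2, and 0.0607 without young leaf replicate 2 or young leaf replicate 3. It was also 0.05 without read pairs that had 3 or more methylated CHH calls, and 0.05 or 0.0536 as a mean over cytosines with at least 10 or at least 5 calls. With the replicate number as a block it was 0.0556.

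**Figure D1:**
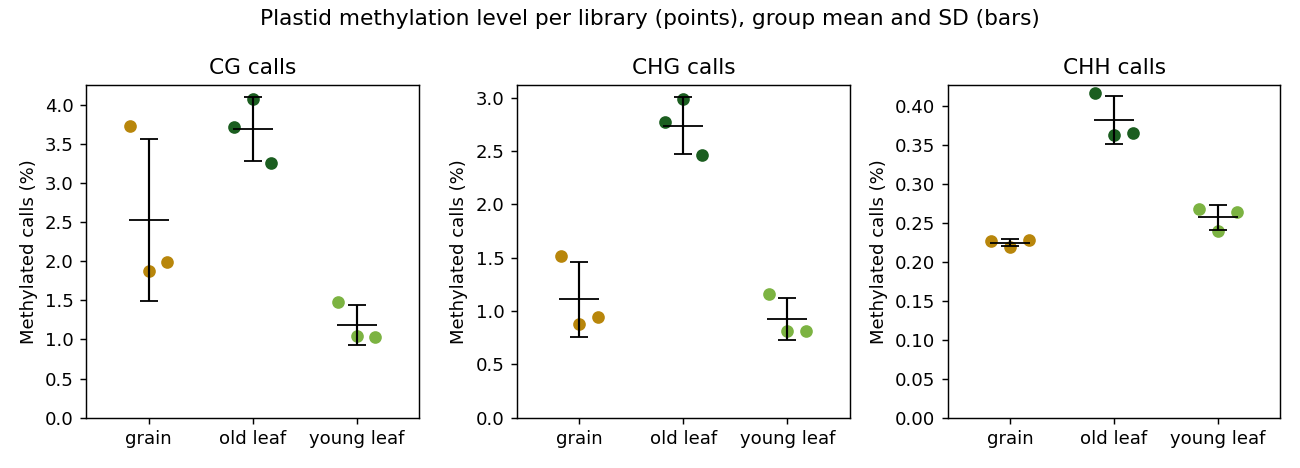
Share of CG, CHG and CHH calls that were methylated (%, vertical axes starting at 0) in each of the 9 libraries (points) of grain, old leaf and young leaf, with the group mean and SD (bars). The 3 old leaf libraries lie above the 3 young leaf libraries in every context, and grain replicate 1 lies at 3.73% for CG against 1.88% and 1.99% in the other 2 grain libraries.

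Levels followed the order CG, CHG, CHH within every library. CG exceeded CHG by 0.875 ± 0.616 percentage points (SD over 9 libraries), and CHG exceeded CHH by 1.3 ± 0.83 points. CG exceeded CHH by 2.18 ± 1.18 points. All 9 libraries showed each direction, with a two-sided exact sign-flip permutation p of 0.00391, the smallest possible. Without read pairs with at least 50% of 2 or more CG calls methylated, these differences shrank to 0.0301, 0.0223 and 0.0524 points, with exact permutation p from 0.135 to 0.176. No unmethylated spike-in was named in the sources used here, so the level that unconverted cytosines contribute was not measured separately.

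The CHG level relative to the CG level was lower in grain than in leaf. The ratio of both levels was 0.449 ± 0.0371 (SD, n = 3) in grain, 0.743 ± 0.0104 in old leaf and 0.782 ± 0.00349 in young leaf, with an exact permutation p of 0.00357 over the 3 groups. This ratio was computed after the levels had been seen.

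Along the plastid sequence, the difference between old and young leaf was spread over many regions for CG and CHG, and over fewer for CHH. Of 114 windows of 1000 bp, 68 were higher in old leaf for CG, 62 for CHG and 22 for CHH at an adjusted p threshold of 0.05 in limma, and 0 were lower in any context. The median log2 odds ratio over windows was 1.5 for CG, 1.38 for CHG and 0.37 for CHH. Relative to the median window of each library, 0 windows differed for CG, 1 was higher for CHG and 1 was higher for CHH, and 0 were lower. In 67 windows for CG, 56 for CHG and 27 for CHH, all 3 old leaf libraries lay above all 3 young leaf libraries, where chance gives 10% of windows without overlap in either direction. Without young leaf replicate 3, the deepest library, the CG count was 36. The CHH count was 10 without old leaf replicate 1 and 13 without old leaf replicate 2. Without weights the counts were 33, 11 and 0, and with calls thinned to equal numbers they were 35 for CG and 30 for CHG.

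Among windows past the threshold, those with the largest log2 odds ratio between old and young leaf lay in separate parts of the sequence. Positions 103001 to 104000 had a CHG level of 5.64% ± 2.44 in old leaf and 0.695% ± 0.611 in young leaf (SD, n = 3), a log2 odds ratio of 3.07 with an SE of 0.74 and a limma adjusted p of 0.00610. Positions 64001 to 65000 had a CG level of 4% ± 1.83 against 0.477% ± 0.278, and positions 54001 to 55000 had 1.77% ± 1.81 against 0.333% ± 0.112. For CHG, positions 36001 to 37000 stood at 2.18% ± 1.77 against 0.386% ± 0.152, and positions 46001 to 47000 at 1.87% ± 0.555 against 0.254% ± 0.229. None of these 5 relative to the median window passed the threshold, with adjusted p from 0.347 to 0.621. Without young leaf replicate 3, the window at 36001 alone among them passed, with adjusted p from 0.0523 to 0.0833 for the other 4. The window at 54001 also had an adjusted p of 0.222 without old leaf replicate 2. All 5 lost the call without read pairs with at least 50% of 2 or more CG calls methylated, with adjusted p from 0.124 (at 36001) to 0.821 (at 54001), and at 64001 the log2 odds ratio turned to -0.45.

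Grain was lower than old leaf over many windows, in CHG above all. At the same threshold, 25 windows were lower in grain for CHG, 13 for CG and 18 for CHH, and 0 were higher. The median log2 odds ratio over windows was -1.39 for CHG, -0.72 for CG and -0.53 for CHH. On a scale relative to the median window of each library the split was different: for CG 10 windows were higher and 2 lower in grain, for CHG 6 were higher and 0 lower, and for CHH 0 differed in limma, with 12 at an unadjusted p under 0.05. The CG count was 0 without grain replicate 2, grain replicate 3 or old leaf replicate 2, 7 without old leaf replicate 3 and 8 without young leaf replicate 3. The CHG count was 14, 7 and 11 without grain replicates 1, 2 and 3 in turn and 38 without young leaf replicate 1. The CHH count was 4, 0 and 6 without grain replicates 1, 2 and 3, and 6 and 10 without old leaf replicates 1 and 2. The counts for CHG, CG and CHH were 6, 1 and 4 in a quasi-binomial model and 40, 2 and 14 without weights, and with thinned calls 48 CHG windows were called. With the replicate number as a block, 20 CG windows were called, 2 of them higher and 18 lower in grain. Likewise 2 CG windows were higher in grain with thinned calls and without read pairs that had 3 or more methylated CHH calls.

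Among windows past the threshold, the largest falls in log2 odds from old leaf to grain were all in CHG. Positions 61001 to 62000 stood at 0.170% ± 0.113 in grain and 2.75% ± 0.545 in old leaf (SD, n = 3), a log2 odds ratio of -3.65 with an SE of 0.96 and a limma adjusted p of 0.0258. Positions 39001 to 40000 stood at 0.484% ± 0.198 against 4.57% ± 1.23, with a log2 odds ratio of -3.22, an SE of 0.49 and a limma adjusted p of 0.00407. Positions 27001 to 28000, 41001 to 42000 and 110001 to 111000 had CHG levels of 0.149% ± 0.0337, 0.195% ± 0.0916 and 0.960% ± 0.329 in grain. The levels there in old leaf were 1.89% ± 1.19, 1.76% ± 0.941 and 7.38% ± 4.19. All of these but the window at 39001 lost the call when any single grain library was left out, with adjusted p from 0.0624 to 0.16. The window at 41001 also lost it without old leaf replicate 1, at 0.0527. The adjusted p of the 5 relative to the median window ranged from 0.198 to 0.418. All 5 lost the call without read pairs with at least 50% of 2 or more CG calls methylated, with adjusted p from 0.29 (at 110001) to 0.991 (at 39001). The log2 odds ratio was then -0.18 at 39001, but -3.83 at 110001, where the fall did not shrink.

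Against young leaf, grain was higher in 14 windows for CG and 4 for CHG, with 0 lower and a median log2 odds ratio of 0.83 and -0.10. For CHH, 0 windows differed in limma and 9 had an unadjusted p under 0.05. Relative to the median window, grain was higher in 8 and lower in 4 windows for CG, and higher in 8 and lower in 0 for CHG. The CG count was 7 without grain replicate 1 and 9 without young leaf replicate 3. The CG and CHG counts were 6 and 2 in a quasi-binomial model and 5 and 0 without weights. Among windows past the threshold, the 5 with the largest log2 odds ratio lay between positions 91001 and 98000. They lie within positions 81001 to 100000, where the median depth of windows in young leaf was 3.91 ± 0.75 times that elsewhere, which makes the threshold easier to pass. A difference of similar order outside this part was the CG level at 7001 to 8000, at 3.43% ± 1.05 in grain and 0.555% ± 0.300 in young leaf. Positions 91001 to 99000 held 252184 of 548920, 192371 of 477755 and 228836 of 783351 CG calls in young leaf replicates 1, 2 and 3. In grain they held 28191 of 140548, 35325 of 196893 and 25435 of 164519. In old leaf they held 49547 of 179374, 31386 of 154726 and 40551 of 183434. Whether the concentration of young leaf read pairs there also affects its level was not tested. At 92001 to 93000 the CG level was 8.19% ± 3.17 in grain and 1.10% ± 0.0846 in young leaf (SD, n = 3), a log2 odds ratio of 3.04 with an SE of 0.27 and a limma adjusted p of 2.26e-05. The CHG level of the same window was 4.12% ± 1.53 against 0.852% ± 0.0826. At 97001 to 98000, 96001 to 97000 and 91001 to 92000 the CG levels were 4.51% ± 1.80, 3.15% ± 1.23 and 4.74% ± 2.38 in grain. In young leaf they were 0.888% ± 0.176, 0.625% ± 0.189 and 0.971% ± 0.334. Without read pairs with at least 50% of 2 or more CG calls methylated, the CG window at 97001 and the CHG window at 92001 lost the call, with adjusted p of 0.0879 and 0.818.

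These windows belonged to a stretch of the plastid sequence, positions 91001 to 99000, in which CG and CHG levels in grain were raised relative to the rest of the sequence. Relative to the median window of each library, 8 neighbouring windows from 91001 to 99000 were higher in grain than in old leaf for CG. The 8 windows higher in grain than in young leaf for CHG were these same positions, and 6 of them were higher than in old leaf for CHG on this scale. As a whole, a measure chosen after these windows had been seen, the stretch had a CG level of 4.88% ± 1.94 in grain against 2.00% ± 0.764 over the rest of the sequence (SD, n = 3). The ratio of the level inside to that outside was 2.44 ± 0.207 in grain, 0.914 ± 0.0737 in old leaf and 0.839 ± 0.104 in young leaf. The lowest grain library, at 2.21, lay above the highest leaf library, at 0.999. For CHG the ratio was 3.17 ± 0.693 in grain, 1.02 ± 0.127 in old leaf and 0.9 ± 0.105 in young leaf. The CHG level itself was no higher in grain than in old leaf there, at 2.47% ± 0.919 against 2.77% ± 0.385, and grain lay below old leaf in 6 of the 8 windows. The CG level inside was 3.43% ± 0.444 in old leaf and 1.05% ± 0.155 in young leaf. The grain libraries stood at 7.12%, 3.81% and 3.70%, overlapping old leaf, whose highest library was at 3.72%. For CHH the ratio of inside to outside was 1.14 ± 0.189, 1.23 ± 0.152 and 0.842 ± 0.0175, highest in old leaf. Inside the stretch old leaf was also above young leaf relative to the median window, for CHG at 92001 to 93000 (log2 odds ratio 0.99, limma adjusted p of 0.0142) and for CHH at 93001 to 94000 (0.84, limma adjusted p of 0.00652). No test was made on these ratios, since the stretch was chosen by its values.

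**Figure D2:**
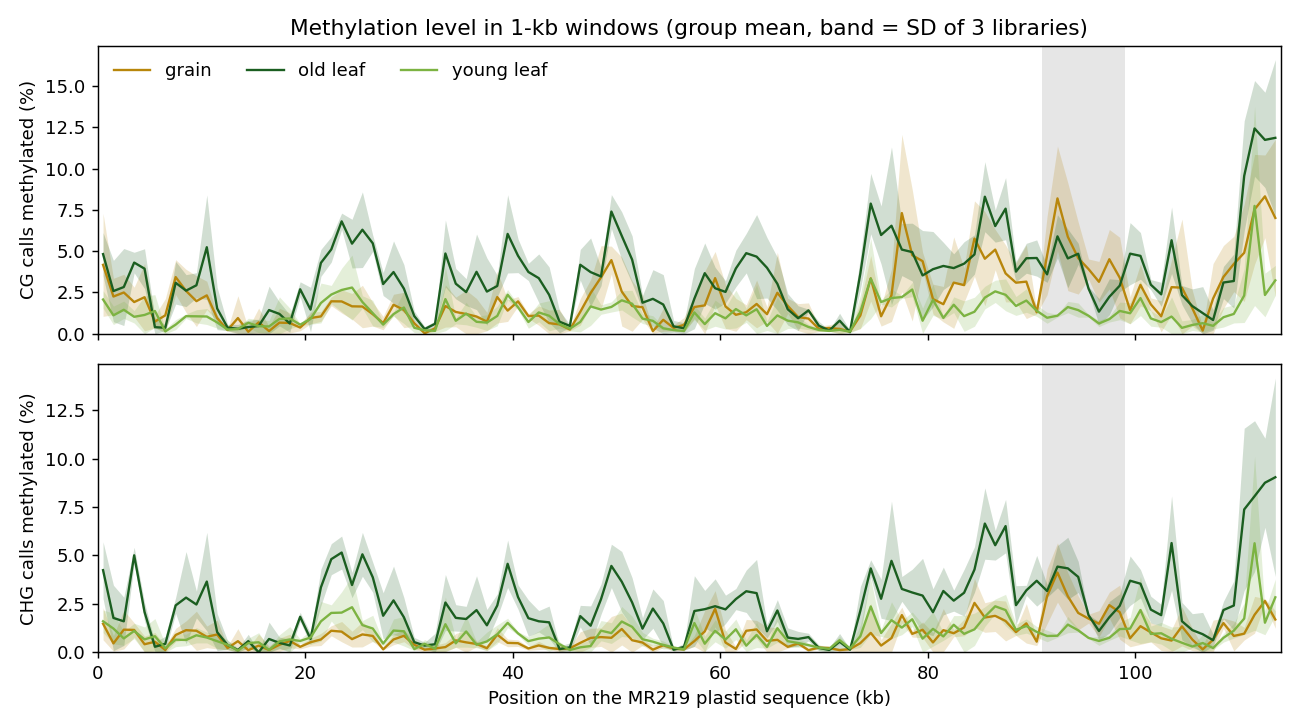
Share of CG calls (upper panel) and CHG calls (lower panel) methylated (%) in consecutive windows of 1000 bp along the MR219 plastid sequence (position in kb), as the mean of the 3 libraries of grain, old leaf and young leaf (lines) and their SD (bands). Shading marks positions 91001 to 99000, where the CG level was 4.88% in grain against 2.00% outside, and the old leaf line runs above the young leaf line along most of the sequence.

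At single cytosines the test depended on depth. At cytosines with at least 10 calls in every library, limma on log-odds placed 1658 CG and 1337 CHG cytosines higher in old than in young leaf and 0 lower, and 1015 CG and 357 CHG cytosines higher in grain than in young leaf and 0 lower. For CHH it called 5702 higher and 1 lower between old and young leaf, and 4910 higher and 1 lower between grain and young leaf. When read pairs were shuffled between libraries so that no difference remained, the same test still called 4516 and 6046 CHH cytosines, 0 and 12 CHG cytosines and 0 CG cytosines. Shuffling leaves counting noise only, so it does not cover the spread between libraries. The CHH counts are therefore not read as differences. The CG and CHG counts, in either direction, also fell with calls thinned to equal numbers, where 2818 CG and 2263 CHG cytosines were tested, to 49 and 67 between old and young leaf and to 311 and 0 between grain and young leaf. Relative to the median cytosine of each library they were 0 and 0, and 143 and 3. Fisher's exact test on calls pooled per group found 471 CG, 217 CHG and 1 CHH cytosines between old and young leaf, and 365, 16 and 0 between grain and young leaf. Pooling takes single calls as replicates, so this test leaves out the spread between libraries. Between grain and old leaf limma called 0 cytosines in each context, with 598, 547 and 1102 at an unadjusted p under 0.05, and Fisher's exact test found 0, 1 and 0.

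Among cytosines past the threshold, those with the largest log2 odds ratio had low levels in every group. The CG cytosines at 58090 and 46524, both on the plus strand, stood at 4.60% ± 7.96 and 7.53% ± 8.76 in old leaf (SD, n = 3), and the CHG cytosine at 10717 on the plus strand at 7.68% ± 7.37. In young leaf the first 2 had no methylated call among 450 and 433, which allows up to 0.667% and 0.693%, and the third stood at 0.134% ± 0.233. Without old leaf replicate 1 the limma adjusted p at 58090 was 0.139. In grain, the CG cytosines at 97636 and 96312 and the CHG cytosine at 92444, all on the minus strand, stood at 3.35% ± 3.03, 7.47% ± 5.36 and 5.49% ± 1.63. Young leaf had no methylated call at these among 765, 356 and 643, which allows up to 0.392%, 0.843% and 0.467%. The rule also names 4 CHH cytosines, which like the other CHH calls are not read as differences, at 93599 and 92393 for old leaf and at 97872 and 91444 for grain, with levels of 5.50% ± 4.77, 1.64% ± 2.84, 1.31% ± 2.26 and 1.18% ± 1.05. Only 93599 among these 4 passed Fisher's exact test, at an adjusted p of 0.0356, and the other 3 had an adjusted p of 1.

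No cytosine was called methylated above the level of its own library in all 3 libraries of a group, in any context, by a one-sided exact binomial test at an adjusted p threshold of 0.01. At an unadjusted p under 0.05, 19 CG cytosines reached this in grain, 21 in old leaf and 8 in young leaf. The corresponding numbers were 6, 20 and 6 for CHG and 0, 7 and 0 for CHH. In single libraries the test called at most 1 CHG cytosine in grain, 5 CG cytosines in old leaf and 25 CG cytosines in young leaf. With calls thinned to equal numbers, the highest CG count in a single library was 0 in grain, 3 in old leaf and 0 in young leaf.

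Methylated calls were concentrated in few read pairs. Of read pairs with at least 4 CG calls, 95.2% ± 1.08 in grain, 94.2% ± 0.607 in old leaf and 96.9% ± 0.419 in young leaf carried no methylated CG call (SD, n = 3). Read pairs with at least 80% of these calls methylated, here called CG-methylated, made up 1.73% ± 0.787 in grain, 3.12% ± 0.485 in old leaf and 1.01% ± 0.302 in young leaf. They held 61.4% to 78.4% of all methylated CG calls of a library. The exact permutation p over the 3 groups was 0.00714 for the share of CG-methylated pairs, with an adjusted value of 0.0429 over 12 measures of read pairs, all chosen after the data had been seen. When every read pair with at least 50% of 2 or more CG calls methylated was left out, which lowers levels by construction, the CG level was 0.330% ± 0.0349 in grain, 0.260% ± 0.0553 in old leaf and 0.185% ± 0.0114 in young leaf. The adjusted 3-group p was then 0.0643 for CG, 0.150 for CHG and 0.575 for CHH, and the windows called between old and young leaf numbered 4, 9 and 1. Between grain and old leaf 0 windows were called in each context. Between grain and young leaf the CG windows rose from 14 to 26, all higher in grain, and 5 CHG and 0 CHH windows were called. The CG levels were then close to those of CHH, where the test per cytosine depended on depth. Read pairs were not shuffled under this setting, so whether depth contributes to the 26 windows was not checked.

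**Figure D3:**
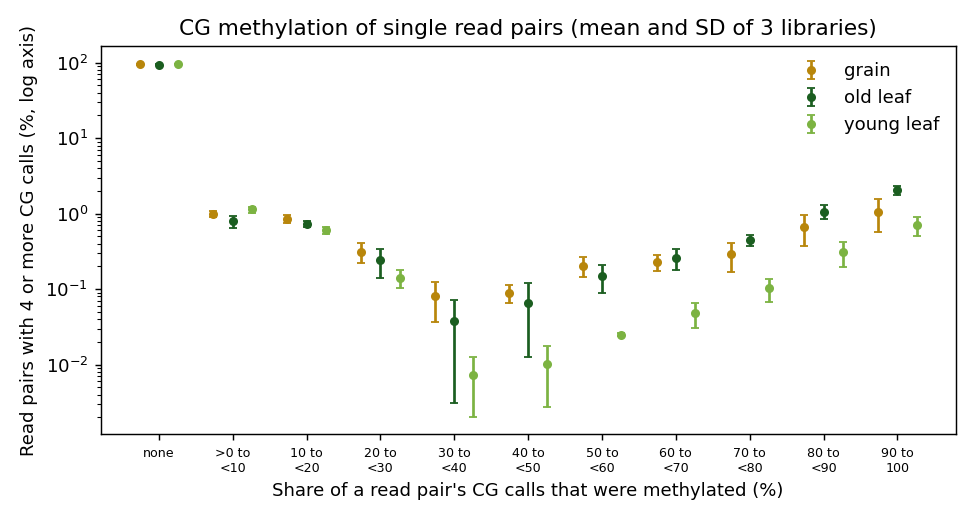
Share of read pairs with at least 4 CG calls (%, log axis) by the share of their CG calls that were methylated (%, each bin including its lower edge), as mean and SD of the 3 libraries of each group. Most pairs (95.2% in grain, 94.2% in old leaf, 96.9% in young leaf) have none, and the shares rise again towards pairs that are methylated throughout.

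Inside CG-methylated read pairs, CHG methylation was lower in grain than in leaf. The CHG level there was 39.4% ± 2.19 in grain, 65.7% ± 1.40 in old leaf and 68.2% ± 1.39 in young leaf (SD, n = 3), with an exact permutation p of 0.00714 and an adjusted value of 0.0429. The CHH level inside them was 0.965% ± 0.1, 4.60% ± 0.465 and 5.05% ± 1.55, with an exact permutation p of 0.0286 and an adjusted value of 0.0551, past the threshold only before adjustment. In pairs with no methylated CG call, the CHG level was 0.193% ± 0.00179 in grain, 0.179% ± 0.0231 in old leaf and 0.164% ± 0.0218 in young leaf, and the CHH level was 0.198% ± 0.0104, 0.2% ± 0.022 and 0.183% ± 0.025. The exact permutation p over the 3 groups was 0.25 and 0.557. For CHG the lowest grain library, at 0.191%, lay just above the highest young leaf library, at 0.189%, with a pairwise exact permutation p of 0.1.

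**Figure D4:**
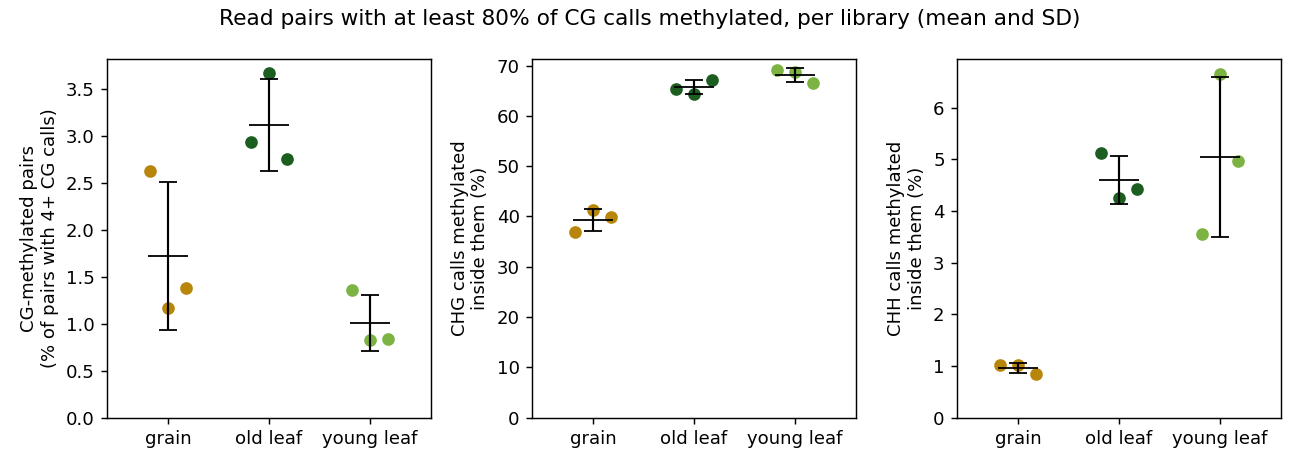
CG-methylated read pairs in each library (points) with group mean and SD (bars): their share of read pairs with at least 4 CG calls (left, %), and the share of CHG calls (middle, %) and CHH calls (right, %) methylated inside them. The CHG level inside these pairs was 39.4% in grain against 65.7% in old leaf and 68.2% in young leaf.

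The read classes fixed in advance also placed old leaf highest for CG-only pairs, a class whose definition leaves CHG calls out and so does not mean unmethylated CHG. Read pairs of the CG-only class, with all of 2 or more CG calls and at most 10% of 5 or more CHH calls methylated, made up 0.774% ± 0.365 in grain, 1.52% ± 0.208 in old leaf and 0.505% ± 0.110 in young leaf (SD, n = 3). The exact permutation p was 0.00714, with an adjusted value of 0.0143 over 2 classes. That value was 0.0607 without old leaf replicate 2 and 0.05 without young leaf replicate 2. Read pairs with over 50% of 5 or more CHH calls methylated, as incomplete conversion would give, were rare: 0.00215% ± 0.00373 in grain, 0.00724% ± 0.00897 in old leaf and 0.0315% ± 0.0106 in young leaf. The exact permutation p was 0.025, with an adjusted value of 0.025. That value rose to between 0.0607 and 0.0714 without grain replicate 2, grain replicate 3, old leaf replicate 2, young leaf replicate 1 or young leaf replicate 2. In 3 libraries (grain replicates 2 and 3, old leaf replicate 1) the count was 0, which allows shares of up to 0.0139%, 0.0165% and 0.0124%.

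Levels were slightly lower on the plus strand, past the threshold for CHH only. The plus strand minus the minus strand was -0.0195 ± 0.016 percentage points for CHH (SD over 9 libraries), below 0 in 8 of 9 libraries, with a two-sided exact sign-flip permutation p of 0.0117 and an adjusted value of 0.0352. The adjusted call was lost when any of 7 libraries was left out in turn, and the difference turned to 0.000126 points without read pairs that had 3 or more methylated CHH calls. For CG the difference was -0.186 ± 0.237 points and for CHG -0.126 ± 0.174 points, with exact permutation p of 0.0508 and 0.0703. Both passed the threshold over cytosines with at least 10 calls, at -0.315 and -0.210 points (adjusted exact permutation p of 0.0117 and 0.0234), and without grain replicate 2 (0.0352 and 0.0469). They turned to 0.0191 and 0.0125 points without read pairs with at least 50% of 2 or more CG calls methylated. The strand difference did not differ between groups, with an exact permutation p of 0.821 for CG, 0.4 for CHG and 0.154 for CHH.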

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

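The setting without read pairs that had at least 50% of 2 or more CG calls methylated, and thinned calls at cytosines, were chosen after the data had been seen; the other settings were fixed before the data were examined. The differences between old and young leaf in the overall level kept their direction in all 3 contexts under every setting run. Pairwise tests of 3 libraries against 3 cannot pass 0.05, so for them only the direction was followed. The cause of the changes below was not tested, except where fewer libraries or fewer calls entered by construction. Depth limits mainly grain and old leaf, whose median depth per CG cytosine was 17 to 25 calls. The level without cytosines called methylated could not be run, as no cytosine met that condition, and the planned comparisons by gene, by gene list and of genes with spacers were not run for want of an annotation of this sequence.

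For the overall level, the adjusted 3-group p for CG was 0.05 without read pairs with 3 or more methylated CHH calls, 0.05 and 0.0536 as a mean over cytosines with at least 10 and at least 5 calls, and 0.0643 without read pairs with at least 50% of CG calls methylated. Leaving out those pairs, chosen by their CG calls, lowers levels by construction. Under that last setting it was 0.15 for CHG and 0.575 for CHH. There, grain exceeded old leaf in CG by 0.0702 percentage points and young leaf in CHH by 0.0104 points, both the opposite of the result with all pairs. Without read pairs with 3 or more methylated CHH calls, grain exceeded young leaf in CHH by 0.00527 points. As a mean over cytosines with at least 5 calls, grain minus young leaf was -0.0936 points in CHG. The differences between contexts shrank to 0.0524 (CG minus CHH), 0.0301 (CG minus CHG) and 0.0223 points (CHG minus CHH) without read pairs with at least 50% of CG calls methylated, and no longer passed the exact sign-flip test. The strand difference turned to 0.0191 (CG) and 0.0125 points (CHG) and fell to -0.00200 points (CHH) without these pairs, and to 0.000126 points (CHH) without pairs with 3 or more methylated CHH calls. Over cytosines with at least 10 calls it passed the threshold, at -0.315 (CG) and -0.210 points (CHG), as it did without grain replicate 2 (adjusted p of 0.0352 and 0.0469, exact sign-flip test).

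Window counts are given as grain against old leaf, old against young leaf, and grain against young leaf. Without pairs with at least 50% of CG calls methylated they were 0, 4 and 26 for CG, 0 and 9 for the first 2 contrasts in CHG, and 0 and 1 in CHH. Whether depth contributes to the 26 at these low levels was not checked. The CG window at 64001 then had a log2 odds ratio of -0.45 between old and young leaf. Without pairs with 3 or more methylated CHH calls, the counts were 5 for CG in grain against old leaf, 7 for CHG in grain against young leaf, and 4 and 12 for CHH in the first 2 contrasts. On the scale relative to the median window they were 0 for CG between old and young leaf, 6, 1 and 8 for CHG, and 0 and 1 for CHH. With thinned calls they were 35 and 8 for CG in the contrasts with young leaf, 48 and 30 for CHG in the first 2 contrasts, and 1 for CHH in grain against young leaf. Without weights they were 2, 33 and 5 for CG, 40, 11 and 0 for CHG, and 0 for CHH between old and young leaf. Windows of 500 bp gave 0, 114 and 23 for CG, 98 and 8 for CHG in the contrasts with young leaf, and 2 for CHH in grain against old leaf. Windows of 2000 bp gave 8 for CG in grain against old leaf. The quasi-binomial model gave 1, 41 and 6 for CG, 6 and 2 for CHG in the contrasts with grain, and 4 and 11 for CHH in the first 2 contrasts. A fit to the 6 libraries of the contrast gave 38 for CHG in grain against old leaf, and a single copy of identical read pairs gave 13 for CHH between old and young leaf.

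Counts of cytosines between old and young leaf and between grain and young leaf moved most. With thinned calls they were 49 and 311 for CG, 67 and 0 for CHG, and 41 and 0 for CHH. Relative to the median cytosine they were 0 and 143, 0 and 3, and 0 and 0. Without weights they were 928 and 663 for CG. With 1 added to each count they were 1531 for CG in grain against young leaf, 2061 and 1081 for CHG, and 9184 and 8466 for CHH. Fisher's exact test on pooled calls gave 471 and 365, 217 and 16, and 1 and 0, with 1 CHG cytosine between grain and old leaf. With at least 20 calls per library, the counts were 840 for CHG between old and young leaf and 3153 and 2586 for CHH, fewer cytosines being tested. Of the 25 windows and cytosines named in the text, 18 lost the call relative to the median feature and 12 with thinned calls, and none changed direction under either. Of the 15 windows among them, 12 lost the call without pairs with at least 50% of CG calls methylated, 1 of which changed direction.

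Leaving out each library in turn gave an adjusted 3-group p of 0.0107 to 0.0607 for CG, a CHG difference between grain and young leaf of -0.0182 to 0.301 points, and strand differences of -0.219 to -0.130 (CG), -0.156 to -0.0942 (CHG) and -0.0223 to -0.0163 points (CHH). The adjusted 3-group p was 0.025 to 0.0714 for incompletely converted read pairs and 0.00714 to 0.0607 for CG-only read pairs. Cytosines called methylated in every remaining young leaf library numbered 0 to 1 for CG and 0 to 2 for CHG. Windows called were 0 to 13, 36 to 81 and 7 to 17 for CG in the order of contrasts above, 7 to 38 for CHG in grain against old leaf, and 0 to 25, 10 to 31 and 0 to 2 for CHH. Cytosines called between old and young leaf were 796 to 2037 for CG, 763 to 1678 for CHG and 3385 to 7217 for CHH. Between grain and young leaf they were 481 to 1103, 73 to 367 and 2309 to 6263.

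Libraries of the same replicate number deviated together in grain and old leaf but not in the contrasts with young leaf, and 3 of 9 libraries correlated best with their own number over the other groups. Grain and young leaf libraries of different numbers correlated at up to 0.19, so these values do not decide whether the numbers pair the libraries. With the replicate number as a block, the adjusted 3-group p for CG was 0.0556, 20 CG windows were called between grain and old leaf (2 higher and 18 lower), and 7 CHG windows between grain and young leaf; no other call or count moved past its limit.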

Other observations

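Tests of incomplete conversion, the comparison of old with young leaf inside CG-methylated read pairs and all descriptions of regions were chosen only after the results were seen; the others were written down before their result was known. Methylation was uneven along the plastid sequence in every group. The highest window for CG lay near the end of the sequence in each of them, at 112001 to 113000 in grain (8.32% ± 2.50, SD, n = 3) and at 111001 to 112000 in old leaf (12.4% ± 2.90) and young leaf (7.74% ± 6.03). The lowest windows lay at 31001 to 32000 in grain (0.0326%) and at 72001 to 73000 in old leaf (0.108%) and young leaf (0.131%). Depth was also uneven. The median depth of windows from 81001 to 100000 was 2.13 ± 0.268 times that of the other windows in grain, 2.34 ± 0.142 times in old leaf and 3.91 ± 0.75 times in young leaf. These positions were chosen by their depth, so no test was made. The stretch from 91001 to 99000, where CG and CHG levels in grain were raised relative to the rest, lies within it. Without read pairs with at least 50% of CG calls methylated, the ratio of the CG level inside that stretch to the level outside was 1.31 ± 0.0924 in grain, 0.879 ± 0.134 in old leaf and 0.978 ± 0.0177 in young leaf. The CHG ratio was then 1.09 ± 0.121, 0.944 ± 0.233 and 0.863 ± 0.0656, with grain and old leaf overlapping.

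The first pattern weighed is the higher CG level in old leaf and grain than in young leaf; without read pairs with at least 50% of 2 or more CG calls methylated, a filter set by the CG calls themselves, it was 0.33% in grain, 0.26% in old leaf and 0.185% in young leaf, with an adjusted 3-group p of 0.0643. Incomplete bisulfite conversion would raise CHH as much as CG, but the CHH difference between old and young leaf was 0.0499 times the CG difference, which argues against it as the whole cause. A candidate explanation is that copies of plastid DNA outside the plastid, such as those in the nuclear genome, were aligned to the plastid sequence: CG-methylated read pairs lacked calls at plastid cytosines 2.05 times as often as unmethylated pairs did at the same positions (1.88 to 2.36 in the 9 libraries), though this is a small difference, 0.401% against 0.195% of calls, and only 3 of 7392 cytosines were missing in at least 50% of these pairs. A missing call was counted whatever its reason, so read errors were not told apart from differences in sequence. A difference from C to T would be read as an unmethylated call and was not counted. A single population of CG-methylated pairs, with 1 CHG level, beside different amounts of plastid DNA is argued against over the 3 groups. The CHG level inside CG-methylated pairs differed between them (exact permutation p of 0.00714). Between old and young leaf this population cannot be told apart (exact permutation p of 0.2, where 3 libraries against 3 allow 0.1 at best). Different amounts of plastid DNA beside pairs whose CHG level depends on the tissue are not covered by this test and stay open. CG-methylated pairs numbered 531 to 577 in old leaf and 353 to 628 in young leaf libraries. Pairs with no methylated CG call numbered 14375 to 18514 and 41239 to 71487, but reads outside the plastid were not counted. Methylation of plastid DNA itself that depends on age or tissue stays open as well and was not tested.

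The second pattern is the lower CHG level relative to CG in grain. Coverage of different regions is argued against: with equal weight for every window the highest grain ratio was 0.448, below the lowest leaf ratio of 0.693. Incomplete conversion in leaf is argued against too, since the CHH difference between grain and old leaf was 0.0965 times the CHG difference. The difference in tissue stays open, and a hypothesis is that the methylated read pairs may carry the CHG methylation of the nuclear DNA of each tissue, for which nuclear levels were not analysed here.

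For counts from limma, the 6 libraries of a contrast can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In each comparison with a count above 0, only 1 of the 10 splits, the real grouping, reached its count. For CG windows the real counts were 13 (grain against old leaf), 68 (old against young leaf) and 14 (grain against young leaf), for CHG windows 25, 62 and 4, and for CHH windows 18 and 22 in the first 2, with 0 as the highest of the other splits. Between grain and old leaf, the real split parts all 3 pairs of the same replicate number; the other splits that do so also gave 0, and the rest keep 2 such pairs together. For CHH windows between grain and young leaf the real count was 0 and another split gave 3. For cytosines, the real counts in the contrasts with young leaf were 1658 and 1015 for CG, 1337 and 357 for CHG and 5703 and 4911 for CHH, with 1 as the highest other for the first CHG contrast and 0 elsewhere. In the contrasts with young leaf only the real split separates deep from shallow libraries, in every context, so these splits do not separate group from depth there. For CHH cytosines they decide nothing, since with no difference present 4516 and 6046 CHH cytosines were still called. For CG and CHG, shuffled read pairs gave 0 CG cytosines and 0 and 12 CHG cytosines, but the counts in the data fell with calls thinned to equal numbers. Between grain and old leaf all 10 splits gave 0 cytosines in each context.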
